A study of Mus musculus with 3 samples.

How the data were processed

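RNA of mouse ovaries was measured on 3 two-colour Agilent whole mouse genome arrays. Per the labels' protocols, ovaries were placed in RNAlater, homogenised and extracted with a Qiagen RNeasy kit, and total RNA was amplified and labelled with Agilent's low input linear amplification kit. Per the labels, each array carried a pool of 3 cKO animals in cy3 and a pool of 3 control animals in Cy5. The pools differ between arrays: control pools 2, 3 and 1 and cKO pools 4, 5 and 7 were on arrays 1, 2 and 3. Each array was taken as 1 replicate of the within-spot ratio of cKO over control, with its number from the sample title. On arrays 2 and 3 the number after the Cre name in 1 genotype label follows the array's number; these arrays were grouped by their titles and the series' design text. Pairing of genotypes is by array, since both pools share each spot. The p-values of single genes reflect the spread between 3 pools per genotype, not between single animals.

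Spot and local background intensity values, deposited as scanned, come from Agilent Feature Extraction 9.1.3.1, per the file headers. Processed intensity values in the same deposited files had been corrected for local background, detrended and dye-normalised with a linear and a LOWESS step on rank-consistent probes, per the file headers. The deposited log10 ratios are of the red over the green processed signal, so of control over cKO. The value table of the series holds these same log10 values for all 45018 features on each of the 3 arrays (largest difference 0), with a median of 0 on each array; its scale, centring and direction are thereby known. Other steps by the authors are not given in the sources used here.

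Each array held 45018 features, of which 1486 were positive and 153 negative controls, leaving 43379 spots of 41174 different probes. Mean spot signals were corrected with median local background by normexp with an offset of 50 and normalised within each array by loess, control spots having weight 0, in limma 3.58.1 under R 4.3.3. The offset pulls ratios of dim probes toward 0. Loess assumes that most genes at a given intensity do not differ. Spots marked by the scanner software as non-uniform or population outliers (13, 4 and 0 on arrays 1 to 3) were left out, and replicate spots of a probe were averaged. The median SD of the log2 ratio among replicate spots was 0.190, 0.141 and 0.183, over 245 probes. Probes well above background in the cKO channel on all 3 arrays or in the control channel on all 3 arrays were kept. Each gene was read by its probe of highest mean log2 intensity; 6193 genes had more than 1 kept probe. Among named genes, Hpgd, Inha, Krt8, Nkg7, Per2, Prlr and Tagln, 7 in number, have a second probe of opposite sign. After normalisation the SD of log2 ratios over genes was 0.45, 0.43 and 0.54 on arrays 1 to 3.

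Spots were named through a table of RefSeq genes of the assembly GRCm38.p6, used for names only: 26788 by their accession, 6252 by their symbol and 1806 by a synonym that belongs to 1 gene. The remaining 8533 kept the name in the file, which dates from the array's design. Genome coordinates of probes were not used here.

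Log2 ratios of cKO over control were tested against 0 with limma's lmFit and eBayes (intercept only, 3 arrays), two-sided, with Benjamini-Hochberg adjustment over 17853 genes and a threshold of 0.05. No dye term could be fitted, because every array has cKO in cy3. Gene lists were tested with camera at a preset correlation of 0.01 against all other genes tested, with camera at an estimated correlation, and with fry, adjusted over the 30 lists. The preset form takes its degrees of freedom from the genes tested. Its p-values therefore reflect the spread across genes and not that between pools. With 3 arrays the estimated form rests on few degrees of freedom, so a list could hardly pass by it. Members were also counted after adjustment over the list alone. In 12 lists some members were not tested, being too dim or without a probe under their symbol. The lists cover the clock (E-box arm, ROR/REV-ERB arm, other clock genes), steroidogenesis, cholesterol synthesis, cholesterol uptake and storage, gonadal hormone receptors and inhibins, luteolysis, prostaglandin synthesis, ovulation, and markers of luteal, granulosa and theca cells, oocytes, endothelium, macrophages, lymphocytes, smooth muscle, fibroblasts, oviduct epithelium, ovarian surface epithelium, erythroid cells and adipocytes. They also cover hypoxia and angiogenesis, immediate early and heat shock genes, the cell cycle, antioxidant defence, oxidative phosphorylation, the interferon response, and Nr5a1 with its neighbours.

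Genes were named by a rule. It takes Arntl, the 12 genes with the highest and the 12 with the lowest log2 ratio among those past the threshold with a gene symbol, the same sign on all 3 arrays and a brighter channel well above background on all 3. Predicted genes were named only where no other symbol was left. From each list it takes up to 4 members past the threshold, or else the 2 with the largest log2 ratio in size, given as values. It adds Star, Cyp11a1, Hsd3b1, Akr1c18, Lhcgr, Prlr, Per2, Dbp and Nr1d1 whatever their values; genes outside it are marked as named after their values were seen, where they appear. The grouping, the fit, the lists, the rule and all alternatives but one were fixed before the data were examined.

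The alternatives were no background correction, normexp with an offset of 10, the scanner's processed signals, median centring in place of loess, scale normalisation between arrays, no filter on dim probes, a filter on both channels, outlier spots kept, the mean over a gene's probes, an intensity trend in eBayes, unpaired single channels, the slide as a block, the slide of arrays 2 and 3 alone, each replicate left out, the series' value table, a fold minimum of 1.5, and an adjusted p of 0.10. Removal of each array's lowess trend on the GC content of the probe was added after the data were seen.

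The procedure was tested on simulated arrays made from the real intensities, with 50 genes changed at each of 4 fold sizes among 17853 and a spread drawn from the real genes. It called 0% of genes changed 1.5-fold, 2% at 2-fold, 36% at 4-fold and 46% at 8-fold. The median estimate over the true log2 ratio was 0.658, 0.794, 0.887 and 0.868. Of the 42 genes called, 0 were unchanged and 0 had the wrong direction, and the 1 list given a shift was called in its direction. In the simulation genes varied independently of each other, and the dye effect was a smooth curve on intensity. It therefore does not show how often genes that vary together, or dye effects specific to a probe, give false calls. At each of the 4 fold sizes more of the changed genes were missed than called.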

Results

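Transcripts of whole mouse ovaries were compared between females lacking the clock gene Bmal1 (symbol Arntl) in cells that express the Cre recombinase under the Sf-1 promoter and females carrying the floxed alleles without Cre. SF-1, the product of Nr5a1, is the nuclear receptor that marks steroid-producing cells of the gonads and the adrenal. All females were 10 weeks old, of the C57Bl/6J strain, and were killed 3.5 days after copulation at Zeitgeber time 12, the time of lights off, when corpora lutea are forming and secrete progesterone. The conditional knockout (cKO) RNA of 3 animals was pooled and hybridised in cy3 against a pool of 3 control animals in Cy5 on each of 3 arrays, so 9 animals of each genotype were measured as 3 pools. The question, from the series title, is what loss of BMAL1 in the peripheral reproductive axis does; here it is asked of the ovary. Array 1 lay on one slide and arrays 2 and 3 on another. The median spot signal over its local background was 2.8, 2.66 and 2.42 on arrays 1 to 3 in the cKO channel and 2.36, 1.8 and 2.12 in the control channel. Spots well above background made up 68.5%, 69.1% and 67.4% in the cKO channel and 65.8%, 62.9% and 64.4% in the control channel. The number of arrays limits the precision of every value. No dyes were swapped, so the effect of the dye on a probe and the effect of genotype cannot be told apart. Values are log2 ratios of cKO over control, as mean ± SD over the 3 arrays (n = 3).

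The targeted gene itself, Arntl, gave log2 ratios of 0.27, 0.13 and -0.24 on arrays 1 to 3, a mean of 0.06 ± 0.27 (limma, adjusted p = 0.932). It was read by 1 probe, well above background in both channels on all 3 arrays. Which part of the gene the floxed allele removes is not stated in the labels, so this probe may lie outside the deleted part and checks neither the deletion nor the labels. Within the slide of arrays 2 and 3 the mean was -0.053.

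Star, the transport protein that delivers cholesterol to the inner mitochondrial membrane for steroid synthesis, had the largest change among genes past the threshold: it was 17.0-fold lower in the cKO ovaries, at -4.09 ± 0.13 (adjusted p = 0.0196), and its second probe also gave -4.09. Lower too were Pik3c2g, a class II phosphoinositide kinase (-3.47 ± 0.52), the tight junction protein Cldn18 (-3.03 ± 0.15), apolipoprotein F (Apof, -2.90 ± 0.34), Etos1 (-2.88 ± 0.36) and neuropeptide B (Npb, -2.73 ± 0.25). Smaller falls were measured for the cystatin Cst8 (-2.46 ± 0.29), Ms4a10 (-2.33 ± 0.35), the transcriptional co-regulator Cited1 (-2.28 ± 0.27), the elastase Cela1 (-2.23 ± 0.31), the folate enzyme Aldh1l1 (-2.11 ± 0.24) and the chloride intracellular channel Clic3 (-2.08 ± 0.13). Among higher genes, Dner, a neuronal Notch ligand, led with 3.22 ± 0.54, or 9.30-fold. It was followed by the alpha-2A adrenergic receptor Adra2a (2.86 ± 0.28), the potassium channel subunit Kcnmb4 (2.85 ± 0.23), Galntl5 (2.76 ± 0.22), the G protein gamma subunit Gng13 (2.62 ± 0.42) and the endoplasmic reticulum peptidase Ermp1 (2.56 ± 0.30). The predicted gene LOC100039836 (2.43 ± 0.33), the vasodilator peptide adrenomedullin (Adm, 2.19 ± 0.05), the ubiquitin ligase Rnf125 (2.03 ± 0.28), Lrp11 (1.99 ± 0.13), Lratd1 (1.94 ± 0.16) and Tmem26 (1.90 ± 0.20) were also higher.

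**Figure D1:**
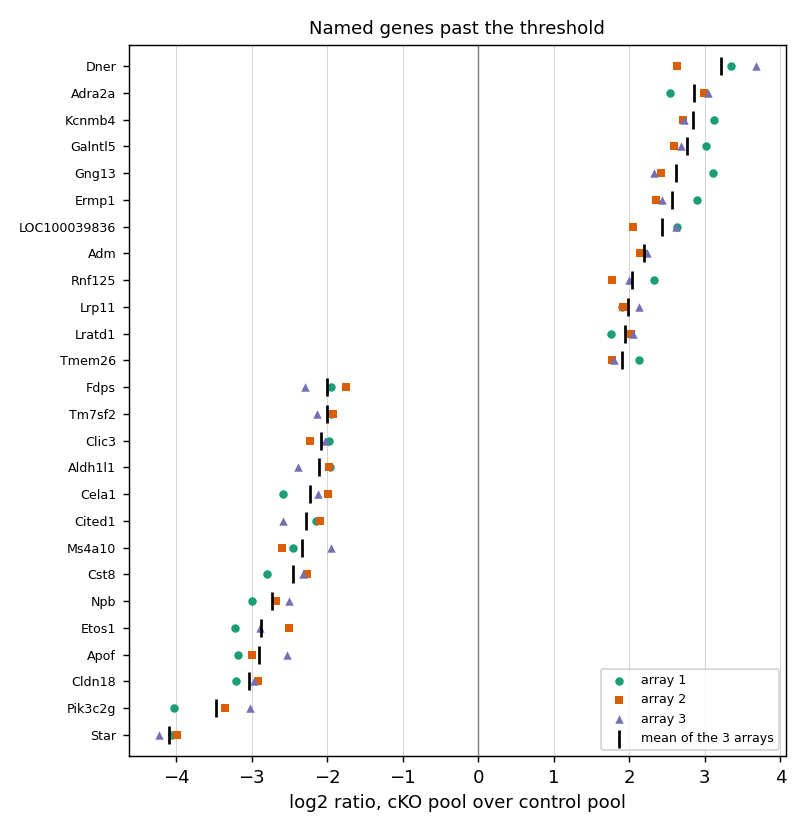
Log2 ratios of cKO over control (horizontal axis) of the 26 genes named here that passed the threshold, 1 gene per line; circles, squares and triangles are arrays 1, 2 and 3, and the black bar is their mean. Each gene lies on the same side of 0 on all 3 arrays, from Star at -4.09 to Dner at 3.22.

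In all, 31 of the 17853 genes tested passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 12 higher by 3.72-fold to 9.30-fold (adjusted p 0.0358 to 0.0467) and 19 lower by 3.32-fold to 17.0-fold (adjusted p 0.0196 to 0.0493). All 31 had the same sign on all 3 arrays. At an unadjusted p under 0.05, 1055 genes were higher and 1149 lower. The lower genes also include Tm7sf2 and Fdps, taken up with cholesterol synthesis, and 5 others named after their values were seen: Bpifb6 (-1.96), the microtubule protein Mapt (-1.87), Ssu2 (-1.86), Mcrip2 (-1.73) and an expressed sequence without a gene symbol. Other probes that passed the filter on dim probes read 11 of the called genes. These 15 probes all had the sign of the probe used. Of them 2 gave under 0.5 of that probe's log2 ratio, 1 of Adra2a (1.34) and 1 of Ermp1 (0.96). Probes that failed the filter were not counted, and those of Pik3c2g (0.006 and 0.03) and Ermp1 (0.23) lay nearer 0 than the probe used. LOC100039836 was well above background in the control channel on 2 of the 3 arrays, so its ratio rests partly on dim spots; with the scanner's own processed signals it was 4.89, and Tmem26 was 3.20. With the slide as a block, 26 genes were higher and 22 lower, 30 of the 31 among them; within the slide of arrays 2 and 3 alone, limma called 0 genes, with 773 at an unadjusted p under 0.05. The calls lie close to the threshold: Star alone passed after median centring in place of loess, and 0 genes passed after scaling the arrays to a common spread (2303 at an unadjusted p under 0.05), without a filter on dim probes (3181), without replicate 1 (773) or without replicate 3 (4855). Without replicate 2, 9 were higher and 6 lower, and the scanner's own processed signals gave 27 higher and 26 lower (50.9% higher, against 38.7%).

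Cholesterol synthesis fell as a group. The list holds genes of the mevalonate and sterol pathway and its regulators Insig1 and Srebf2. All 21 genes had a mean below 0, and 18 of them were negative on all 3 arrays. The regulators, named after their values were seen, were not among these 18 and lay near 0 (-0.13 ± 0.13 and -0.16 ± 0.32). The list's median was -0.69 (limma camera, adjusted p = 8.8e-17 with a preset correlation and adjusted p = 0.323 with an estimated correlation). Over all genes tested, 2 members passed, both lower: the sterol reductase Tm7sf2 (-2.01 ± 0.12, adjusted p = 0.0392) and farnesyl diphosphate synthase, Fdps (-2.00 ± 0.27, adjusted p = 0.0467). Adjusted over the list alone, 18 passed, all lower. The list's median was -0.57, -0.65 and -0.84 on arrays 1 to 3, -0.65 with the slide as a block and -0.72 within the slide of arrays 2 and 3. Its adjusted p was 0.0088 by fry.

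Steroidogenesis and the uptake and storage of cholesterol did not pass as groups. Of 16 steroidogenic genes 1 passed, Star, over all genes and adjusted over the list alone alike; the median was -0.05 (adjusted p = 0.206). The enzymes that follow Star, the side-chain cleavage enzyme Cyp11a1 and the dehydrogenase Hsd3b1, were at -0.30 ± 1.11 (adjusted p = 0.848) and -0.38 ± 0.23, and neither passed. The control spot of Hsd3b1 was saturated on 1 of the 3 arrays, so a difference there is compressed and its ratio and test may understate a fall. Cyp11a1 differed between arrays: 0.39, 0.28 and -1.59, with its other probes at means of -0.06 and -0.41. Among 15 genes of cholesterol uptake and storage, 0 passed over all genes and 0 adjusted over the list alone, with a median of -0.08 (adjusted p = 0.452). Their largest values were the cholesterol exporter Abcg1 at 0.86 ± 0.44 and the lipoprotein receptor Scarb1, which supplies luteal cells with cholesterol, at -0.80 ± 0.77.

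Among clock genes, the 4 repressed by REV-ERB and activated by ROR receptors were higher as a group, with a median of 0.77 (adjusted p = 4.9e-04, but adjusted p = 0.651 with an estimated correlation) and 1.03, 0.57 and 0.74 on arrays 1 to 3. Cry1, a repressor of BMAL1-driven transcription, stood at 1.30 ± 0.52 and Nfil3 at 0.98 ± 0.30. Over all genes 0 of the 4 passed, and adjusted over the list alone 3 did, Npas2 (0.55 ± 0.21) with them, a gene outside the rule for named genes. The adjusted p of this list was 0.108 by fry; its median was 0.83 with the slide as a block and 0.64 within the slide of arrays 2 and 3. Of the 14 genes whose promoters carry E-boxes bound by BMAL1, the largest values in size were Nr1d2 at -2.01 ± 0.31 (adjusted p = 0.0506), Dbp at -1.43 ± 0.05 (adjusted p = 0.0506) and, on the other side of 0, Cry2 at 1.42 ± 0.65 (adjusted p = 0.236), named after its value was seen. Nr1d1, which encodes REV-ERB alpha, was at -1.36 ± 0.47 (adjusted p = 0.183), while its other probes, 2 dimmer ones, gave -0.19 and -0.23. None passed over all genes. Adjusted over the list alone 4 did, Nr1d2, Dbp and Nr1d1 lower and Cry2 higher. Per2 was at 0.03 ± 0.04, and the list's median of -0.14 did not pass (adjusted p = 0.0732). Of 6 other clock genes, 0 passed over all genes and 2 adjusted over the list alone, Rora (1.11 ± 0.30, other probes at 1.35 and 0.32) and Fbxl21 (0.75 ± 0.41); their median was 0.20 (adjusted p = 0.117).

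**Figure D2:**
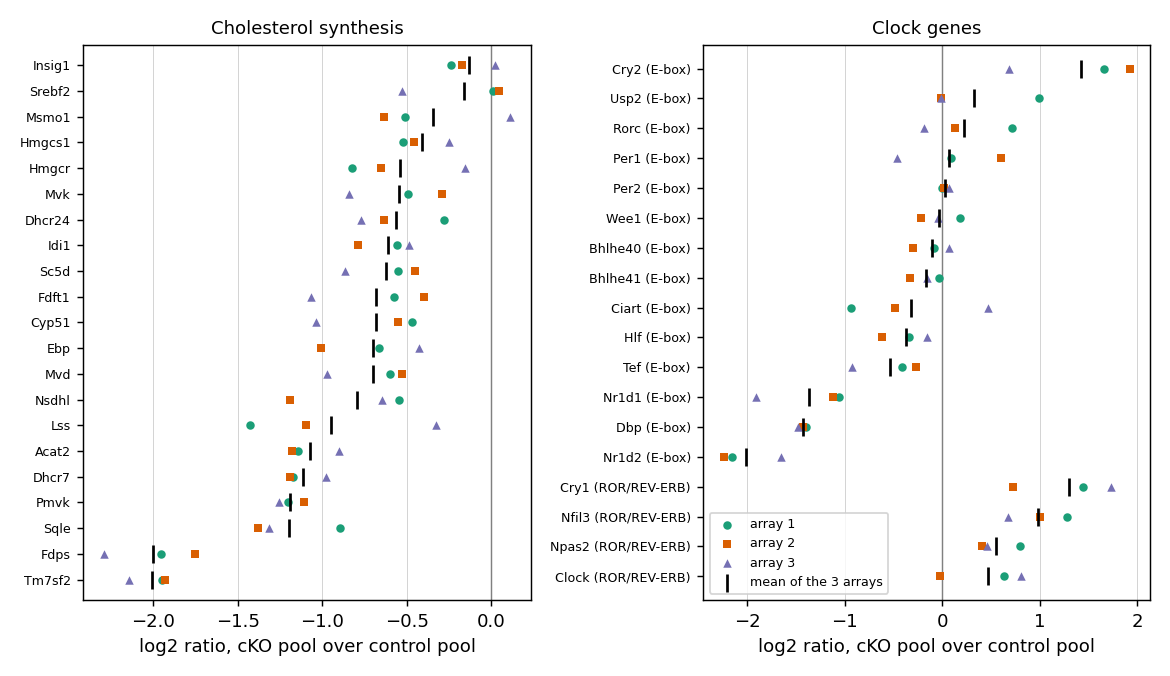
Log2 ratios of cKO over control (horizontal axes) of the 21 cholesterol synthesis genes (left) and of the 14 E-box and 4 ROR/REV-ERB clock genes (right); circles, squares and triangles are arrays 1, 2 and 3, and black bars are means of the 3 arrays. All 21 bars on the left lie below 0, and on the right Nr1d2, Dbp and Nr1d1 lie between -2.01 and -1.36 while the 4 ROR/REV-ERB genes have means above 0.

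Receptors and luteal genes showed values on both sides of 0. Among 13 gonadal hormone receptors and inhibins the prostaglandin F receptor Ptgfr was at 1.07 ± 0.30, with a second probe at 0.25 (-0.18 on array 2), the oxytocin receptor Oxtr at -1.06 ± 0.14, with a second, dimmer probe at -0.25, the luteinizing hormone receptor Lhcgr at -0.86 ± 0.07 (adjusted p = 0.164) and the prolactin receptor Prlr at -0.04 ± 0.13. None of the 13 passed over all genes; adjusted over the list alone 4 did, Ptgfr higher and Oxtr, Lhcgr and Esr1 lower, Esr1 (-0.87 ± 0.26) being named after its value was seen. Their median was -0.14 (adjusted p = 0.0926). Akr1c18, the enzyme that inactivates progesterone and marks the regressing corpus luteum, gave 2.85, -0.38 and 2.64 on the 3 arrays, a mean of 1.70 ± 1.81 (adjusted p = 0.426). Without replicate 2 its mean was 2.74 and passed (adjusted p = 0.0459), so array 2 decides that call. Of the 10 luteolysis genes 0 passed over all genes and 1, Ptgfr, adjusted over the list alone, and the median was 0.14 (adjusted p = 0.140). Among 10 ovulation genes the largest values were the protease inhibitor Timp1 at 2.28 ± 0.40 (adjusted p = 0.0506) and the protease Adamts1 at 0.76 ± 0.21, its second probe at 0.15. Both passed adjusted over the list alone, 0 did over all genes, and the median was 0.22 (adjusted p = 0.0647). For 11 prostaglandin synthesis genes the median was 0.06 and the mean -0.08 (adjusted p = 0.947); prostaglandin D synthase, Ptgds, at -1.42 ± 0.33, was the 1 that passed adjusted over the list alone, 0 passed over all genes, and Hpgd was at -0.50 ± 0.38 with its second probe at 0.18.

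Genes of antioxidant defence were lower as a group. The median of 14 genes was -0.40 (adjusted p = 1.2e-04, but adjusted p = 0.623 with an estimated correlation), with -0.19, -0.40 and -0.69 on arrays 1 to 3, and 9 of them were negative on all 3. Mitochondrial superoxide dismutase, Sod2, was at -1.53 ± 0.32 and heme oxygenase, Hmox1, at -1.17 ± 0.53; 0 members passed over all genes, and 5 adjusted over the list alone, all lower. The other three of these, named after their values were seen, were Sod1 (-0.45 ± 0.09), Gpx1 (-0.71 ± 0.38) and Prdx1 (-0.83 ± 0.23). The control spot of Sod1 was saturated on 1 of the 3 arrays. The list's adjusted p was 0.108 by fry, and its median was -0.32 with the slide as a block and -0.51 within the slide of arrays 2 and 3.

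Fibroblast and fibrillar matrix genes were higher as a group, with a median of 0.53 over 10 genes (adjusted p = 0.0070, but adjusted p = 0.706 with an estimated correlation). The fibrillar collagens Col5a1 (1.25 ± 0.15, second probe 0.14) and Col1a1 (1.02 ± 0.40, second probe 0.36) had the largest values; 0 members passed over all genes and 3 adjusted over the list alone, Col3a1 (0.59 ± 0.12), named after its value was seen, being the third. The median was 0.67, 0.88 and 0.16 on arrays 1 to 3. Macrophage (0.72, 0.77 and -0.71) and smooth muscle markers (0.20, 0.80 and -0.98) also were higher on arrays 1 and 2 and lowest on array 3, so a larger share of such cells and higher expression within fibroblasts cannot be told apart. Without replicate 2 it was 0.21 and did not pass (adjusted p = 0.0712). The adjusted p was 0.241 by fry; the median was 0.52 with the slide as a block and 0.49 within the slide of arrays 2 and 3.

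Markers of the other ovarian cell types did not pass as groups. Luteal cell markers (10 genes, 8 of them in other lists as well) had a median of -0.17 (adjusted p = 0.336); 1, Star, passed over all genes and 4 adjusted over the list alone, Star and Lhcgr lower and Ptgfr and Sfrp4 higher, Sfrp4 (0.61 ± 0.29) being named after its value was seen. For granulosa cells (12 genes, median -0.11, adjusted p = 0.408) the largest values were Inha at -0.45 ± 0.27, with a second probe at 0.45, and aromatase, Cyp19a1, at 0.43 ± 1.24. Theca cell markers (6 genes) had a median of 0.03 and a mean of -0.10 (adjusted p = 0.695), with Ptch1 at -0.47 ± 0.27 and Bmp4 at -0.45 ± 0.78. Oocyte markers (19 genes) had a median of -0.07 (adjusted p = 0.695), with Zar1 at -0.60 ± 0.14 and Oosp1 at -0.60 ± 1.04. Endothelial markers (14 genes) had a median of -0.04 (adjusted p = 0.695), with Eng at 0.52 ± 0.38 and Robo4 at 0.47 ± 0.43. In the granulosa, theca, oocyte and endothelial lists 0 members passed over all genes and 0 adjusted over the list alone.

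Macrophage markers (13 genes) had a median of 0.23 (adjusted p = 0.336), with lysozyme, Lyz2, at 1.38 ± 1.01 and Fcgr1 at 0.74 ± 0.47, its second probe at 0.08. Lymphocyte markers (11 genes) had a median of -0.03 and a mean of 0.03 (adjusted p = 0.740), with Gzmb at 0.46 ± 0.14 and Nkg7 at 0.32 ± 0.14, a second Nkg7 probe giving -0.12. For smooth muscle (10 genes) the median was -0.03 and the mean 0.03 (adjusted p = 0.983), with Tagln at 0.62 ± 1.26, its second probe at -0.29, and Smtn at -0.29 ± 0.43. Markers of oviduct epithelium (7 genes, median 0.06, adjusted p = 0.714) included Ovgp1 at -0.42 ± 2.62 and Cdh1 at 0.31 ± 0.98. The ovarian surface epithelium list (8 genes) had a median of 0.04 and a mean of -0.01 (adjusted p = 0.947), with Krt8 at -0.59 ± 0.63, its second probe at 0.18, and Krt19 at -0.54 ± 1.20. Erythroid markers (3 genes, median -0.14, adjusted p = 0.336) included Hba-a1 at -0.65 ± 0.49 and Slc4a1 at -0.14 ± 0.21. Adipocyte markers (7 genes, median 0.13, adjusted p = 0.336) included lipoprotein lipase, Lpl, at 1.61 ± 0.47, which alone passed adjusted over its list, and Plin1 at 0.69 ± 0.47. Over all genes 0 members of these lists passed, and apart from Lpl 0 passed adjusted over the list alone.

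The arrays differed from each other in these markers. Besides the macrophage and smooth muscle medians given with the fibroblast list, the surface epithelium median was 1.13, -0.45 and -0.64 and the oocyte median -0.12, -0.31 and 0.38 on arrays 1 to 3. Over the 17853 genes, which are not independent replicates, Pearson's r was 0.601 between arrays 1 and 2, 0.213 between arrays 1 and 3 and 0.00874 between arrays 2 and 3, the pair on one slide. Genes with the same sign made up 71.4%, 53.5% and 45.6% in these comparisons. The scanner's own log ratios over all probes gave 0.350, 0.0508 and -0.201. Each gene group reported here was measured on these same arrays.

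**Figure D3:**
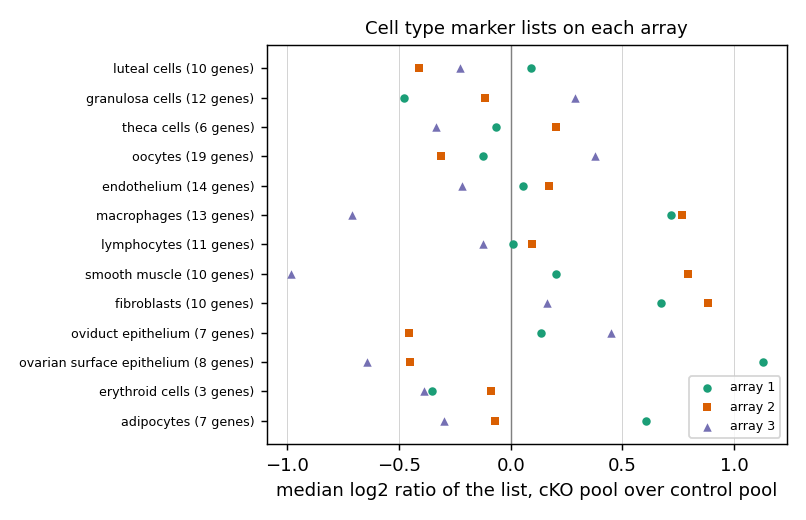
Median log2 ratio of cKO over control (horizontal axis) of each of the 13 cell type marker lists, 1 list per line with its number of genes; circles, squares and triangles are arrays 1, 2 and 3. On array 3 macrophage and smooth muscle markers lie at -0.71 and -0.98, below their values on arrays 1 and 2, and oocyte markers at 0.38 lie above theirs.

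Stress, proliferation and metabolic lists did not pass as groups either. In the hypoxia and angiogenesis list (12 genes) the median was -0.02 and the mean 0.25 (adjusted p = 0.417); Adm passed over all genes, and 3 passed adjusted over the list alone, Adm and Egln3 (1.65 ± 0.18) higher and Bnip3 (-0.67 ± 0.27) lower, the last pair named after their values were seen. Immediate early and heat shock genes (14 genes) had a median of 0.17 (adjusted p = 0.239), with the phosphatase Dusp1 at -1.23 ± 0.29 and the transcription factor Egr2 at 1.20 ± 0.39; 0 passed over all genes and 4 adjusted over the list alone, Egr1 (0.56 ± 0.09) and Ier2 (0.55 ± 0.19), named after their values were seen, with them. Cell cycle genes (17 genes) had a median of -0.27 (adjusted p = 0.101) and of -0.61, -0.39 and 0.43 on arrays 1 to 3. Without replicate 3 the median was -0.59 and the list passed (adjusted p = 2.5e-05). It did so in 3 of 18 alternatives in all, some of which repeat the same analysis. Members included Mcm6 at 0.77 ± 0.84 and Ccna2 at -0.59 ± 0.60. Oxidative phosphorylation genes (16 genes) had a median of -0.07 (adjusted p = 0.207), with the complex III subunits Uqcrc2 at -0.57 ± 0.22 and Uqcrc1 at -0.42 ± 0.22. Interferon response genes (10 genes) had a median of -0.24 (adjusted p = 0.239), with Bst2 at -1.20 ± 0.29, the 1 member that passed adjusted over the list alone, and Ifit3 at -0.59 ± 0.40. Nr5a1 and its chromosomal neighbours (12 genes) had a median of -0.02 and a mean of 0.11 (adjusted p = 0.695), with Nr6a1 at 1.28 ± 0.77 and Nr5a1 at 0.51 ± 0.67. In the cell cycle, oxidative phosphorylation and neighbour lists 0 members passed over all genes or adjusted over the list alone, and in the interferon list 0 passed over all genes.

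Of the 30 gene lists, 4 passed with the preset correlation, 2 lower and 2 higher, and 0 did with an estimated correlation, where adjusted p ran from 0.323 to 0.995. The estimated form rests on the few degrees of freedom of 3 arrays, so its 0 does not by itself show that correlation between genes made the shifts. For cholesterol synthesis and antioxidant defence the estimated correlation (-0.044 and -0.0072) lay below the preset 0.01. Their unadjusted camera p still rose, from 2.9e-18 to 0.011 and from 7.8e-06 to 0.042. The preset form takes its degrees of freedom from the genes, so its small p-values do not measure the spread between pools. For the ROR/REV-ERB and fibroblast lists the estimate was 0.333 and 0.433, above it. By fry, which asks whether a list's own genes move one way and does not compare them with other genes, 1 list passed, cholesterol synthesis. By camera with the preset correlation, the 26 lists that did not pass had adjusted p from 0.0647 to 0.983. In 7 lists the median and mean had opposite signs; both are given for each. Of the 4 lists that passed, cholesterol synthesis and antioxidant defence stayed below 0 and the ROR/REV-ERB and fibroblast lists above 0 in each of the alternatives run. Each of these medians already had one sign on all 3 arrays, so leaving out arrays could hardly turn it. Their kept signs are therefore no test of direction.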

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

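The removal of the trend on probe GC content was chosen after the data were seen. The 31 called genes each had one sign on all 3 arrays, so leaving out arrays cannot turn them and their kept signs are no test of direction. A gene not chosen so can turn: Cyp11a1 went from -0.30 to 0.34 without replicate 3. Against 12 higher and 19 lower genes, no background correction gave 20 and 24, normexp with an offset of 10 gave 28 and 29, the scanner's processed signals and the series' value table each gave 27 and 26, an intensity trend in eBayes 37 and 42, and removal of the GC trend 21 and 25. The unpaired fit, with no replicate block, gave 65 and 78, the slide as a block 26 and 22, and an adjusted p of 0.10 in place of 0.05 gave 29 and 34. A filter on both channels gave 18 and 23 and the mean over a gene's probes 14 and 22; keeping outlier spots or asking for at least 1.5-fold gave 12 and 19. Fewer passed with median centring in place of loess (0 and 1, Star at -3.97, adjusted p = 0.0373), which moves the median of all genes to 0.12, so ratios there are relative to that shift. With limma, 0 and 0 passed with scale normalisation between arrays (2303 genes at an unadjusted p under 0.05, lowest adjusted p 0.0603), with no filter on dim probes (3181 at an unadjusted p under 0.05, and 27966 genes tested), and on the slide of arrays 2 and 3 alone (773 at an unadjusted p under 0.05, and 1 array fewer). Leaving out each replicate in turn gave 0 to 9 higher and 0 to 6 lower genes; without replicate 2, 12 of the 31 remained.

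Gene lists passed in number 4 with the values reported. There were 11 with the scanner's processed signals and 11 with the value table, 7 with no filter, 8 with the mean over probes, 7 with the slide as a block, 8 on the slide of arrays 2 and 3, and 8 to 8 with each replicate left out. With an estimated correlation 0 passed and with fry 1. Of the lists that did not pass, some passed in part of 18 alternatives: ovulation in 9, the E-box arm in 8, interferon response in 4, and cell cycle, luteolysis, hormone receptors and inhibins and other clock genes in 3 each. Macrophages, surface epithelium, smooth muscle, steroidogenesis and immediate early genes passed in 2 each, granulosa cells and oviduct epithelium in 1 each. These tallies count some analyses more than once. The slide of arrays 2 and 3 and the removal of replicate 1 use the same arrays. The scanner's processed signals and the value table hold the same ratios. The mean of Arntl reversed to -0.053 on the slide of arrays 2 and 3, which are the arrays left without replicate 1, and ran from -0.053 to 0.20 with each replicate left out; it was far from the threshold throughout. The mean correlation between arrays was 0.274 and ran from 0.00782 to 0.600 with each replicate left out, the highest without replicate 3. Apart from the smaller number of arrays and the looser threshold, the cause of these moves was not tested. The larger number of genes tested without a filter is not the whole cause there. The lowest adjusted p (limma) rose from 0.0196 over 17853 genes to 0.0929 over 27966, by more than the number of genes did. Signal over background, between 1.8 and 2.8 at the median spot, limits ratios of dim probes: LOC100039836 ran from 2.34 to 4.89 over the alternatives, Tmem26 from 1.78 to 3.20 and Dner from 2.99 to 4.66, while Star, a bright gene, ran from -4.14 to -3.97.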

Other observations

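The test for exchanged RNA on array 3 and the removal of the GC trend were chosen after the results were seen, as were the genes named in the opening paragraphs here. Genes with an adjusted p (limma) between 0.05 and 0.10 are given here as values and not as calls. Among those with a gene symbol and the same sign on all 3 arrays, S100g and Prl had the largest ratios in size. The others given are a selection: Timp1 and Nr1d2 appear above, and Slc41a3 (1.90 ± 0.37) is among those left out. The vitamin D-dependent calcium-binding protein S100g was at 4.29 ± 1.07 (adjusted p = 0.0790, higher on 3 of 3 arrays). The prolactin transcript Prl was at 2.77 ± 0.69 (adjusted p = 0.0872), well above background in the control channel on 1 array only, so its size is uncertain. The vessel peptide apelin (Apln) was at 2.18 ± 0.51, the oxygen-sensing hydroxylase Egln3 at 1.65 ± 0.18, the adrenergic receptor Adra2c at 1.77 ± 0.21, the hyaluronan receptor Cd44 at 1.62 ± 0.33 and the tubulin Tubb6 at 1.57 ± 0.14. On the low side lay the sulfotransferase Chst1 (-1.98 ± 0.33), the cadherin Cdh15 (-1.83 ± 0.25), the triglyceride enzyme Dgat2 (-1.47 ± 0.24), the cholesterol synthesis enzyme Pmvk (-1.19 ± 0.07) and the thromboxane receptor Tbxa2r (-1.13 ± 0.03).

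Some single transcripts, chosen because they did so, took opposite signs on array 3 and on arrays 1 and 2. The nuclear RNA Malat1 gave 0.54, 1.99 and -2.89 on arrays 1 to 3, and Meg3 gave 0.40, 1.20 and -1.40. The antigen presentation gene Cd74 gave 1.03, 1.12 and -1.86, H2-Eb1 gave 0.59, 1.19 and -1.68, the phagocyte marker Cd68 gave 1.83, 1.07 and -0.71, and Apoe gave 1.14, 1.39 and -1.51. Other phagocyte markers kept their sign by the probe used: Lyz2 gave 2.46, 1.23 and 0.46, Fcgr1 gave 0.92, 1.08 and 0.20, and Mrc1 gave -0.26, -0.25 and -0.45. A second Fcgr1 probe turned on array 3, at 0.40, 0.57 and -0.73. Inhbb, an inhibin subunit of growing follicles, gave -1.37, -0.46 and 1.51, and the mitosis genes Ncapg and Ect2 gave -0.90, -0.94 and 1.43, and -1.06, -0.87 and 1.17.

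Array 3 shared little with arrays 1 and 2 over all genes, although Star was far below 0 on each. An exchange of cKO and control RNA on array 3 is argued against by the clock genes. The E-box arm minus the ROR/REV-ERB arm was -1.23, -0.83 and -1.33 on arrays 1 to 3. The r of array 3 with the mean of arrays 1 and 2 was 0.126, not below 0. This r decides less, since the scanner's own log ratios over all probes gave 0.0508 with array 1 and -0.201 with array 2. Noisier spots are argued against too, since the median SD among replicate spots on array 3 was 0.964 times that of the noisier of the others. Another cell makeup of a pool on array 3 is a candidate explanation that its test cannot decide. Random lists were drawn gene by gene, while genes of a cell type list can move together. The estimated correlation was 0.823 for macrophages, 0.931 for smooth muscle, 0.976 for surface epithelium and 0.267 for oocytes. These estimates come from the same 3 arrays, so a joint shift of a list on 1 array itself raises them. They are therefore no separate evidence on the test. Lists whose genes move together leave the random range more easily, and arrays 1 and 2 were not put through the same test. Of 13 cell type lists, 4 deviated on array 3 by more than the central 99% of 10000 random lists matched on intensity. These were macrophages (-1.38), smooth muscle (-1.54) and surface epithelium (-1.01) downward and oocytes (0.63) upward. The surface epithelium value comes from array 1, which stands apart from arrays 2 and 3 (medians 1.13, -0.45 and -0.64), and so says nothing of array 3. These lists share no gene with other lists, of their abundant members Lyz2 was lowest but above 0 on array 3 and Acta2 gave 0.45, 1.25 and -1.09, and, as each value is a ratio, either pool may differ; luteal (-0.10) and granulosa cell lists (0.51) lay within their random ranges, the latter near its upper end of 0.54, so a difference in the number of follicles stays open, and, as the design holds no group for it, no biological explanation was tested further.

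The 31 called genes rest on 3 arrays of a single dye orientation. With the sign of 1 array turned, the highest count was 0 against the real 31; with 4 orientations (1 of them, the real one, giving 31 or more) these are too few for a share under 0.05. A dye bias that follows the GC content of the probe was looked at by removing that trend. The share of called genes still called was then 1 (31 of 31). The trend was weak and differed between arrays (r = 0.0653, 0.109 and -0.224 across genes). The called genes had log2 ratios of -1.73 and below or 1.90 and above, so its removal could hardly turn their signs. A call could still have been lost, since their adjusted p (limma) lay between 0.0196 and 0.0493. Removal moved the number of genes called from 31 to 46. The result shows only that a trend of this size does not make their ratios, and is no further test of dye bias. Removal left r at 0.599 between arrays 1 and 2 and at 0.236 and 0.0377 between these and array 3. Dye effects specific to single probes could still add to any one ratio and cannot be told apart from genotype without swapped dyes.

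Nr5a1 and its neighbours were examined because a large Cre transgene made from that locus may carry extra copies of them; the labels do not say how the transgene was made. Their median was -0.018, with a bootstrap 95% range of -0.07 to 0.14 over 12 genes, 5 above 0 and 7 below. Nr6a1, the gene next to Nr5a1, gave 1.64, 1.80 and 0.40, and Nr5a1 gave 0.81, 0.98 and -0.25. Members going both ways leave extra copies of part of the region open.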
